A study of Folsomia candida with 16 samples.

How the data were processed

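RNA was measured in the springtail Folsomia candida, a small soil-living relative of the insects, with 8 groups of 4 samples. Each sample was a pool of whole animals from 1 jar, aged 23 days at the start of exposure and 25 days at its end, after 2 days in a standard soil spiked with 1 compound or with the solvent alone. The compounds were aniline, 5 anilines with 1 to 5 chlorine atoms, and 1,2,3,4-tetrachlorobenzene, an apolar narcotic without the amino group. The 32 samples were labelled with Cy3 or Cy5 from an input of 500 ng total RNA each and hybridised in pairs on 16 arrays in an interwoven loop, so that every group held 2 Cy3 and 2 Cy5 samples. The labels call the 4 samples of a treatment biological replicates, so the p-values rest on the spread between separate jars.

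Per the file headers, each array was scanned and its spots were measured with Agilent Feature Extraction 9.5.1.1, which gave the mean signal and the local background of each spot as an intensity on a linear scale. The deposited scanner files also hold a log10 ratio of Cy5 over Cy3 per spot, which per the file headers is Agilent's own background-subtracted and dye-normalized value. The authors also deposited a processed value table of the same arrays. Its values, which lacked a stated unit, followed the log2 ratio of Cy5 over Cy3 of the spot on the same line of the scanner file, with r of 0.861 to 0.92 across spots within an array against Agilent's ratio, compared with r of 0.12 to 0.209 when spots were paired by feature number. Spots are not independent replicates, and these r values describe the match only. The slope of these deposited log2 values on the ratio of mean signals was 0.57 to 1.07, and the median of each column was 0 to 0.022. The normalization behind this deposited table is not given in the sources used here. The authors used limma 2.9.2 per the submitters' processing notes, which give no role or setting for it.

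The array held 5069 probes in 3 spots each, 15207 spots in all, beside 536 control spots. Each gene name on the array had 1 probe, and whether probes of different names measure the same transcript was not settled. A description of the best match in a sequence database came with 2321 probes in the files, and 2748 probes had none. All descriptions name genes of other species, so a gene is called by its probe ID with the description as its likeness. None of the 5069 probe IDs (0 found) and none of the 2871 accessions in the descriptions (0 found) was in the table of 27231 RefSeq genes of assembly ASM221717v1, so no gene symbol or position was taken from it. No genome sequence was used here, and no coordinates are given.

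Mean signals were corrected for the median local background by normexp with an offset of 50 and normalized by loess within each array with control spots at weight 0, without a step between arrays. Spots with a non-uniformity or population outlier mark, 3.25% to 3.91% of the spots of an array, were left out, and the 11 saturated spots were kept. The spots of a probe were averaged, and 45 combinations of probe and array had no spot left. Probes were kept where at least 2 of the 3 spots were well above background in at least 4 of the 32 channels. This left 4447 probes, 2098 of them with a description, and took out 622, of which 462 were not well above background in any channel. A total of 3704 probes were well above background in all channels.

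The log2 ratios were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes). The model had a coefficient per compound against the solvent control, which the submitters name as their reference, and a dye term per probe. It had 8 residual and 2.24 prior degrees of freedom. All p-values are from limma's moderated test, two-sided, with Benjamini-Hochberg adjustment within each comparison, and a probe was called changed at an adjusted p under 0.05. Each compound was compared with the control. Further comparisons were all compounds jointly (F test), the linear trend over chlorine number in the 6 anilines, the anilines' mean against tetrachlorobenzene, tetrachloroaniline against tetrachlorobenzene, and the 5 pairs of anilines next to each other in chlorine number. Levels of single samples are background-corrected log2 intensities of 1 channel after loess and quantile normalization of the mean intensity between arrays (Aquantile). Groups, tests, filters, gene lists, named genes and most alternatives were chosen before the data were examined.

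The genes named for each compound were those with the highest and lowest log2 fold changes, up to 10 each way, among probes called changed with the same sign in each of the 16 fits that leave out 1 array. Genes with a description came first, and an undescribed gene was named only when it was among the 2 most changed in a direction. Trend and pairwise comparisons had up to 5 genes each way by the same rule, and each gene list up to 4 genes with the smallest adjusted p in any compound. A gene outside this rule is marked as chosen after its values were seen.

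A total of 24 gene lists were fixed as word patterns on the descriptions. With at least 3 measured genes, 19 lists were tested in the 7 compounds, 133 tests adjusted together, by limma's camera with a preset correlation of 0.01. Camera with an estimated correlation and fry (statmod 1.5.0) were run beside it. The lists cover cytochrome P450, other phase I enzymes, glutathione S-transferases, UDP-glycosyltransferases, sulfo- and acetyltransferases, ABC and drug transporters, antioxidant enzymes, chaperones, proteasome and ubiquitin, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis and citrate cycle, lipid metabolism, cuticle and chitin, digestive enzymes, yolk proteins, muscle, nerve and ion transport, innate immunity, beta-lactam synthesis, metal binding, DNA repair and histones, apoptosis, and microbes.

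The calculation was tested on simulated data of the same design, in which 200 of the 4447 probes were changed in each compound. It recovered 62% to 75% of the probes changed by a log2 of 1 and 87% to 93% of those changed by a log2 of 2. Of the calls, 1.8% to 6.43% were wrong, and 0 of 140 unchanged lists passed 0.05 in camera. The simulated noise was independent between probes, so these rates do not cover probes or list members that vary together. Calls in unchanged groups with that joint variation kept are given with the similarity of the responses.

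The 16 arrays lay on 3 slides with 6, 7 and 3 arrays. Slide was therefore added as a fixed block, and differences were also estimated within a slide from its own arrays after each probe's dye term over all arrays had been subtracted. The block let a probe's dye term differ between slides, since a signal shared by both channels of an array cancels in its ratio. It also used up residual degrees of freedom. A call lost with the block thus does not by itself show that the difference depended on the slide. The within-slide values have no residual degrees of freedom and no test. Called probes were chosen from a fit that held the same arrays, so agreement of their direction within a slide is largely set in advance. The solvent control was on slides 1 and 2, so slide 3 gave differences between compounds alone. Other alternatives were no background correction, Agilent's own log ratio, Aquantile after loess, no filter and a stricter filter, no dye term, array weights, the deposited table, a variance prior with trend and robust fitting, separate channels, marked spots kept, adjustment over all 7 compounds at once, and leaving out each array in turn. Leaving out 2 arrays far apart in the residuals, leaving out single list members, the slide block for the gene lists and the mean of all compounds were chosen after seeing the data. The number of arrays limits the precision. The signal limits it too, with 4020 to 4410 probes well above background in Cy3 and 3963 to 4392 in Cy5.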

Results

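Gene expression was measured in pools of whole springtails after 2 days in soil spiked with 1 of 7 compounds at a dose labelled as its EC50, the concentration with a median effect, or with the solvent alone. The labelled doses were 77.7 µmol/kg for aniline, 74.8 µmol/kg for 4-chloroaniline, 76.8 µmol/kg for 3,5-dichloroaniline, 101.8 µmol/kg for 2,3,4-trichloroaniline, 120.3 µmol/kg for 2,3,5,6-tetrachloroaniline and 163.8 µmol/kg for both pentachloroaniline and 1,2,3,4-tetrachlorobenzene. Whether 1 of these 2 identical labels repeats the other by mistake could not be told, so each comparison that uses them gives the dose as labelled only. The anilines are polar narcotics that carry an amino group on the ring and, in this series, 0 to 5 chlorine atoms. The chlorobenzene, an apolar narcotic, served as the positive control. Each of the 8 groups held 4 samples, and 16 arrays compared them in pairs. The median signal of an array was 227.9 to 440.9 in Cy3 and 517.9 to 1673.2 in Cy5. Samples of a group correlated across probes with r of 0.943 to 0.99, which describes these samples, since probes are not independent replicates.

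The comparison of all 7 compounds with the control asked which genes responded to any of them. A cytochrome P450 gene, Fcc01651, whose best match was the mosquito CYP6N4v1 and whose family oxidises foreign compounds, led the response together with Fcc01695, a gene without a description. Fcc01651 had a mean log2 intensity of 7.39 ± 0.31 (SD, n = 4) in the control, 8.05 ± 0.59 after aniline, 9.14 ± 0.41 after 4-chloroaniline and 10.06 ± 0.29 to 11.27 ± 0.66 in the groups with at least 2 chlorine atoms. Fcc01695 had 6.84 ± 0.19 in the control, where 3 of 4 samples were well above background, and 11.22 ± 0.19 after tetrachloroaniline. In limma's F test, 21 of 4447 probes differed between the groups, with 476 at an unadjusted p under 0.05, and the adjusted p was 4.2e-05 for Fcc01651 and 1.2e-05 for Fcc01695. Among the other genes were the cuticle protein Fcc03188 (adjusted p 0.018), the transporter-like Fcc04544 (0.028) and the sorting nexin-like Fcc01283 (0.0078). The fit with slide as a block called 15. Without the array of aniline replicate 1 and 4-chloroaniline replicate 1 the count was 12, without that of 4-chloroaniline replicate 2 and dichloroaniline replicate 1 it was 11. It was 10 without that of trichloroaniline replicate 2 and tetrachloroaniline replicate 1, and without that of aniline replicate 3 and trichloroaniline replicate 3 it was 12, without that of tetrachloroaniline replicate 4 and control replicate 3 it was 10, and without that of control replicate 4 and dichloroaniline replicate 4 it was 12.

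**Figure D1:**
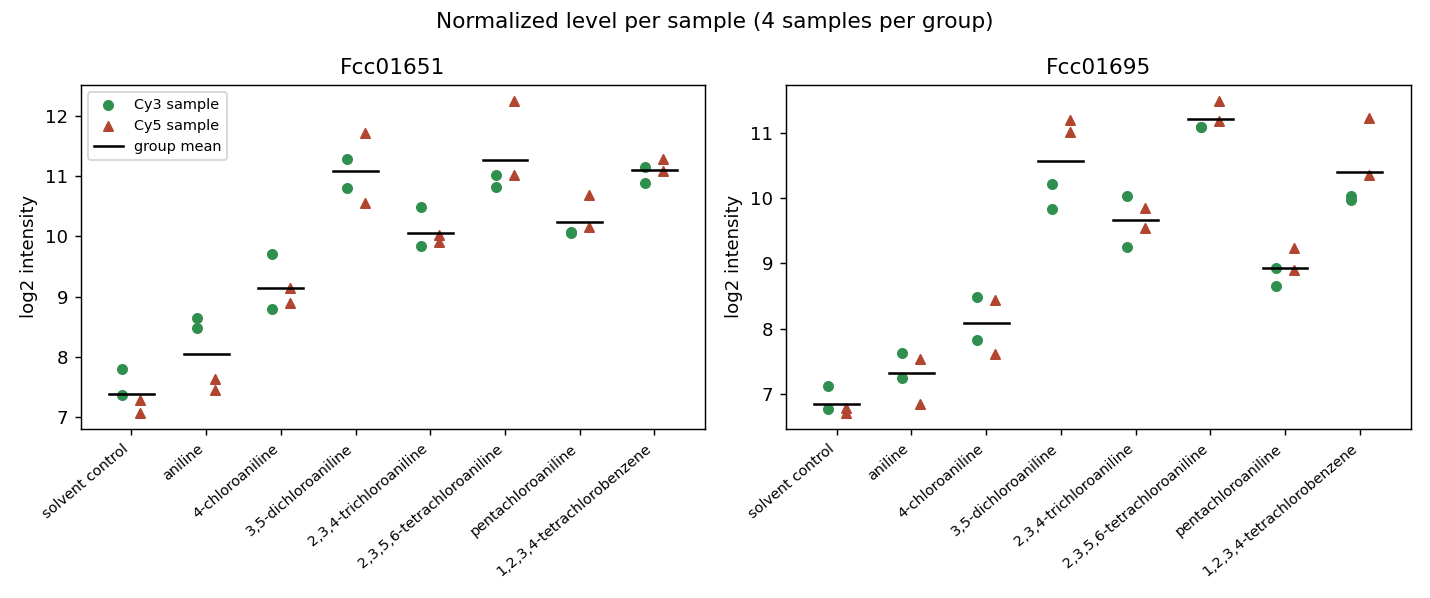
Log2 intensity of the cytochrome P450 gene Fcc01651 and of the undescribed gene Fcc01695 in each sample, by group, with each group's mean. Samples of the control sit lowest and those of tetrachloroaniline, dichloroaniline and tetrachlorobenzene highest, with 1 tetrachloroaniline sample at 12.25 for Fcc01651.

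Aniline, the compound without chlorine, was compared with the control to show the response to the bare ring with its amino group. Both leading genes had small estimates, a log2 fold change of 0.37 ± 0.21 (SE, n = 4) for Fcc01651 (adjusted p 0.62) and 0.52 ± 0.21 for Fcc01695 (adjusted p 0.51). The 36 measured genes in the list of cytosolic ribosomal proteins, parts of the machine of protein synthesis, all had estimates below 0, with a median of -0.224, as the list test below describes. Yolk polypeptide-like Fcc02167 had 1.01 ± 0.26 (adjusted p 0.37). No probe passed the threshold: limma called 0 of 4447 probes, with 398 at an unadjusted p under 0.05, and the fit of separate channels, also in limma, called 6. A slide block in limma also left 0. Leaving out the array of pentachloroaniline replicate 4 and aniline replicate 4 gave 3 calls, that of tetrachloroaniline replicate 2 and pentachloroaniline replicate 1 gave 2, and that of tetrachlorobenzene replicate 2 and control replicate 1 gave 1.

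4-Chloroaniline was compared with the control to show the response to 1 chlorine atom. A pair of genes without a description rose, Fcc03768 by a log2 of 2.18 ± 0.25 (adjusted p 0.012) and Fcc05884 by 2.08 ± 0.23 (adjusted p 0.012), and all 4 exposed samples lay above the control mean for both. Above all control samples lay 2 of the 4 for Fcc03768 and 3 of the 4 for Fcc05884. Fcc01651 stood at 1.22 ± 0.22 (adjusted p 0.12) and the cuticle protein Fcc03188 at 1.25 ± 0.24 (adjusted p 0.14). The 2 calls of limma stood beside 376 probes at an unadjusted p under 0.05, and the fit of separate channels called 14. Blocking by slide, limma called 0, with 2.28 ± 0.28 for Fcc03768 (adjusted p 0.12) and 2.08 ± 0.37 for Fcc05884 (adjusted p 0.48), and the values within slides 1 and 2 were 3.29 and 0.50 for Fcc03768 and 2.16 and 2.01 for Fcc05884. Leaving out 1 array changed the count to 0 for the array of 4-chloroaniline replicate 2 and dichloroaniline replicate 1, for that of 4-chloroaniline replicate 3 and tetrachloroaniline replicate 3 and for that of tetrachloroaniline replicate 4 and control replicate 3. It was 1 for that of control replicate 2 and aniline replicate 2, and 4 for that of tetrachlorobenzene replicate 4 and 4-chloroaniline replicate 4.

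After 3,5-dichloroaniline both leading genes rose, Fcc01695 by a log2 of 3.69 ± 0.21 (12.9-fold, adjusted p 2e-05) and the cytochrome P450 gene Fcc01651 by 2.96 ± 0.21 (7.78-fold, adjusted p 9.6e-05). The undescribed gene Fcc01513 rose by 3.06 ± 0.35 (adjusted p 0.0031), the transporter-like gene Fcc04544 by 1.57 ± 0.2 (adjusted p 0.0076), and Fcc02155 and Fcc00734, both matching mosquito proteins of unnamed function, by 2.68 ± 0.41 (adjusted p 0.03) and 1.5 ± 0.15 (adjusted p 0.001). Fcc01283, similar to sorting nexin 9, a protein of endocytosis, fell by 1.89 on the log2 scale (SE 0.27, adjusted p 0.018). In all, limma called 9 probes, 8 up and 1 down, and for each of the 9 all 4 exposed samples lay beyond the control mean. For 8 of the 9 they lay beyond all control samples. Blocking by slide gave 9 calls, 8 of them the same, with 3.76 ± 0.15 for Fcc01695 and 2.89 ± 0.16 for Fcc01651 and 2.67 ± 0.46 for Fcc02155 (adjusted p 0.15). All 9 had their direction within slide 2, the only slide where this difference could be estimated. The count was 4 without the array of control replicate 4 and dichloroaniline replicate 4.

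After 2,3,4-trichloroaniline both leading genes rose as well. Fcc01695 rose by a log2 of 2.97 ± 0.22 (adjusted p 0.00033), Fcc01513 by 2.4 ± 0.37 (adjusted p 0.04), Fcc01651 by 1.92 ± 0.22 (adjusted p 0.0073) and Fcc00734 by 1.46 ± 0.16 (adjusted p 0.0052). Sorting nexin-like Fcc01283 fell by 2.37 on the log2 scale (SE 0.29, adjusted p 0.0089). Altogether limma called 7 probes, 6 up and 1 down, each with all 4 exposed samples beyond the control mean. For 6 of the 7 they lay beyond all control samples. With slide as a block 3 were called, with 2.78 ± 0.18 for Fcc01695 (adjusted p 0.001), 2.2 ± 0.19 for Fcc01651 (adjusted p 0.0038) -2.17 ± 0.32 for Fcc01283 (adjusted p 0.091) and 2.08 ± 0.39 for Fcc01513 (0.32). All 7 kept their direction within slide 2, where Fcc01651 stood at 1.26. The count was 4 without the array of trichloroaniline replicate 4 and tetrachlorobenzene replicate 3, and 4 without that of tetrachloroaniline replicate 4 and control replicate 3.

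2,3,5,6-Tetrachloroaniline changed the most probes of the 7 compounds in the fit of all arrays. Fcc01695 rose by a log2 of 4.4 ± 0.21 (21.1-fold, adjusted p 3.4e-06) and the cytochrome P450 gene Fcc01651 by 3.52 ± 0.21 (11.5-fold, adjusted p 1.7e-05). A glutathione S-transferase-like gene, Fcc05260, whose family joins glutathione to foreign compounds, rose by 1.55 ± 0.27 (adjusted p 0.031), and the transporter-like gene Fcc04544 by 1.44 ± 0.2 (adjusted p 0.011). Cuticle protein 8-like Fcc03188 rose by 1.38 ± 0.22 (adjusted p 0.026) and prophenoloxidase-like Fcc01326, of a family that starts melanin formation in insect blood, by 1.02 ± 0.18 (adjusted p 0.034). Genes that fell included Fcc00376, which matched a putative cytoplasmic protein (-1.69 ± 0.25, adjusted p 0.015), Fcc01972, similar to the inhibitor of growth family of chromatin proteins (-0.64 ± 0.11, adjusted p 0.027), and Fcc03200, whose shortened description begins with thyroid hormone receptor (-0.59 ± 0.1, adjusted p 0.026). By limma 30 probes changed, 20 up and 10 down, with 728 at an unadjusted p under 0.05, and all 4 exposed samples lay beyond the control mean for 25 of the 30. For 17 of the 30 they lay beyond all control samples. The fit with slide as a block called 10, among them Fcc01695 (4.55 ± 0.18) and Fcc01651 (3.19 ± 0.19, adjusted p 0.00018), whereas Fcc05260 (1.7 ± 0.34, adjusted p 0.082), Fcc03188 (1.33 ± 0.3, 0.11), Fcc01326 (0.92 ± 0.23, 0.13), Fcc04544 (1.41 ± 0.25, 0.072), Fcc00376 (-1.33 ± 0.22, 0.072), Fcc01972 (-0.75 ± 0.13, 0.072) and Fcc03200 (-0.65 ± 0.13, 0.079) were not. All 30 kept their direction within slide 1 and within slide 2. The count was 6 without the array of tetrachloroaniline replicate 4 and control replicate 3, 11 without that of control replicate 4 and dichloroaniline replicate 4. It was 12 without that of 4-chloroaniline replicate 3 and tetrachloroaniline replicate 3, 18 without that of 4-chloroaniline replicate 2 and dichloroaniline replicate 1, and 71 without that of control replicate 2 and aniline replicate 2.

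**Figure D2:**
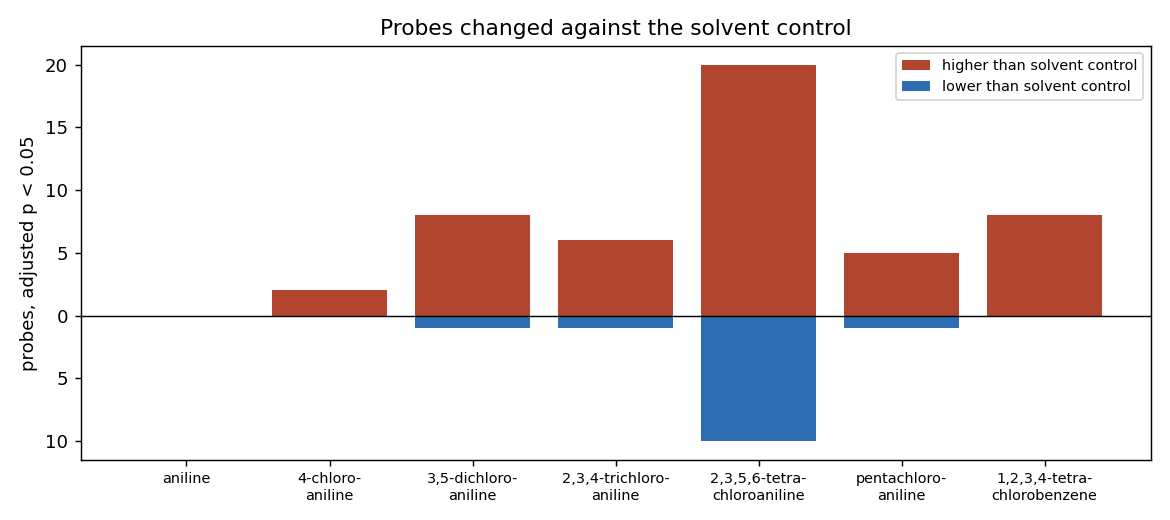
Number of probes with a limma adjusted p under 0.05 against the solvent control in each compound, higher ones above the line and lower ones below it. Tetrachloroaniline had 20 higher and 10 lower, and aniline had 0.

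Pentachloroaniline, with chlorine at each ring position except that of the amino group, raised Fcc01651 by a log2 of 2.6 ± 0.22 (6.06-fold, adjusted p 0.0013), Fcc01695 by 2.2 ± 0.22 (4.61-fold, adjusted p 0.0028) and Fcc00734 by 1.12 ± 0.16 (adjusted p 0.023). Fcc00376 fell by 1.72 on the log2 scale (SE 0.27, adjusted p 0.048). Glutathione S-transferase-like Fcc05260 had 1.22 ± 0.29 (adjusted p 0.39). The 6 calls of limma, 5 up and 1 down, had all 4 exposed samples beyond all 4 control samples. Blocking by slide left 5, with 2.6 ± 0.16 for Fcc01651 and 2.2 ± 0.16 for Fcc01695 and 1.12 ± 0.17 for Fcc00734 (adjusted p 0.085). Within slides 1 and 2 Fcc01651 stood at 2.94 and 2.28. The count was 2 without the array of pentachloroaniline replicate 2 and tetrachlorobenzene replicate 1, 2 without that of dichloroaniline replicate 3 and pentachloroaniline replicate 3. It was also 2 without that of pentachloroaniline replicate 4 and aniline replicate 4, 3 without that of aniline replicate 1 and 4-chloroaniline replicate 1, and 3 without that of trichloroaniline replicate 4 and tetrachlorobenzene replicate 3.

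1,2,3,4-Tetrachlorobenzene, the apolar compound, raised the same leading pair, Fcc01695 by a log2 of 3.89 ± 0.21 (14.8-fold, adjusted p 1.2e-05) and Fcc01651 by 3.56 ± 0.21 (11.8-fold, adjusted p 1.5e-05). Fcc02155 rose by 3.1 ± 0.41 (adjusted p 0.013), Fcc03650, similar to a vertebrate protein of unnamed function, by 2.62 ± 0.38 (adjusted p 0.025), Fcc00734 by 1.68 ± 0.15 (adjusted p 5e-04) and the transporter-like Fcc04544 by 1.25 ± 0.2 (adjusted p 0.048). All 8 probes called by limma rose, and all 4 exposed samples lay above all 4 control samples for each. With slide as a block 6 were called, with 3.77 ± 0.17 for Fcc01651 and 3.78 ± 0.16 for Fcc01695 and 3.08 ± 0.49 for Fcc02155 (adjusted p 0.11), 2.83 ± 0.41 for Fcc03650 (0.067) and 1.28 ± 0.23 for Fcc04544 (0.21). Within slides 1 and 2 Fcc01651 stood at 4.01 and 2.78. The count was 5 without the array of tetrachlorobenzene replicate 2 and control replicate 1, and 5 without that of control replicate 4 and dichloroaniline replicate 4.

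**Figure D3:**
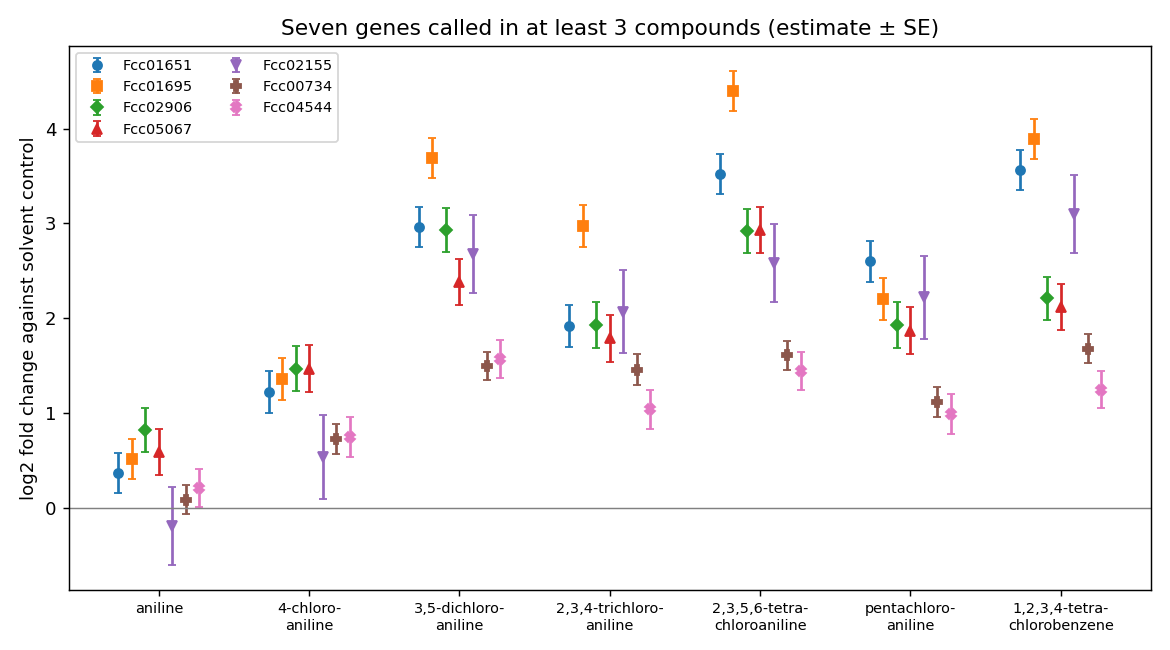
Log2 fold change against the solvent control, with its SE, of 7 genes called in at least 3 compounds, for each compound (4 samples per group). The 7 genes lie lowest after aniline and are highest after the compounds with at least 2 chlorine atoms, with Fcc01695 at 4.4 after tetrachloroaniline.

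The trend over chlorine number asked which genes had a linear slope from aniline to pentachloroaniline. The chlorine positions on the ring changed along with the number, so the 2 cannot be told apart. The cytochrome P450 gene Fcc01651 rose by a mean log2 of 0.49 ± 0.04 per chlorine atom (adjusted p 0.00021), although not at each step, with 0.37, 1.22, 2.96, 1.92, 3.52 and 2.6 from 0 to 5 chlorine atoms, and Fcc02155 by 0.5 ± 0.07 (adjusted p 0.033). Glutathione S-transferase-like Fcc05260 rose by 0.28 ± 0.05 per chlorine atom (adjusted p 0.048) and Fcc00734 by 0.22 ± 0.03 (adjusted p 0.0081), whereas Fcc00376 fell by 0.27 (SE 0.04, adjusted p 0.048). In limma 17 probes had a linear trend, 15 up and 2 down, with 715 at an unadjusted p under 0.05, and the labelled molar dose was 74.8 to 77.7 µmol/kg for the first 3 anilines and rose from 101.8 to 163.8 µmol/kg over the other 3. The fit with slide as a block called 2, Fcc01651 (0.39 ± 0.04, adjusted p 0.016) among them, but not Fcc02155 (0.51 ± 0.12, 0.57), Fcc05260 (0.32 ± 0.07, 0.57), Fcc00734 (0.2 ± 0.04, 0.5) or Fcc00376 (-0.17 ± 0.05, 0.63). All 17 kept their direction within slide 2, where Fcc01651 had 0.51. Leaving out any 1 array gave 2 to 9 probes, except that of 4-chloroaniline replicate 2 and dichloroaniline replicate 1, which gave 21.

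Anilines that differ in chlorine number were then compared with their neighbours, at near-equal labelled doses of 77.7, 74.8 and 76.8 µmol/kg for the first 3 and at rising doses beyond. In some pairs, such as 4-chloroaniline and 3,5-dichloroaniline, the chlorine positions on the ring differed too. Such a step is not one of chlorine number alone. From aniline to 4-chloroaniline, Fcc01381 rose by a log2 of 3.46 ± 0.41 (adjusted p 0.019), Fcc00967 by 2.06 ± 0.27 (adjusted p 0.023) and Fcc00969, similar to an insect protein of unnamed function, by 2 ± 0.25 (adjusted p 0.019), whereas Fcc01651 differed by 0.85 with a 95% interval of 0.39 to 1.31 (adjusted p 0.26). From 4-chloroaniline to 3,5-dichloroaniline, Fcc01695 rose by 2.32 ± 0.21 (adjusted p 0.0018) and Fcc01651 by 1.74 ± 0.21 (adjusted p 0.01), and sorting nexin-like Fcc01283 fell by 2.05 (SE 0.27, adjusted p 0.018) and Fcc01195 by 1.47 (SE 0.15, adjusted p 0.0043). By limma, 3 probes differed in the first pair and 4 in the second, with 345 and 277 at an unadjusted p under 0.05. Blocking by slide turned the counts to 0 and 1, with 2.66 ± 0.24 for Fcc01695 (adjusted p 0.013) and 1.12 ± 0.25 for Fcc01651 (adjusted p 0.62) in the second pair, and with 3.61 ± 0.53 for Fcc01381 (0.13) in the first. Within slides 2 and 3 Fcc01651 differed by 1.94 and 2.05. Leaving out 1 array moved the first count to 0 for the array of aniline replicate 1 and 4-chloroaniline replicate 1, for that of 4-chloroaniline replicate 2 and dichloroaniline replicate 1 and for that of tetrachloroaniline replicate 4 and control replicate 3. It moved it to 1 for aniline replicate 3 with trichloroaniline replicate 3, to 5 for dichloroaniline replicate 2 with trichloroaniline replicate 1, to 6 for 4-chloroaniline replicate 3 with tetrachloroaniline replicate 3, to 9 for tetrachloroaniline replicate 2 with pentachloroaniline replicate 1 and to 27 for tetrachlorobenzene replicate 4 with 4-chloroaniline replicate 4. It moved the second count to 0 for 4-chloroaniline replicate 2 with dichloroaniline replicate 1, to 2 for aniline replicate 1 with 4-chloroaniline replicate 1, for 4-chloroaniline replicate 3 with tetrachloroaniline replicate 3 and for dichloroaniline replicate 3 with pentachloroaniline replicate 3, to 7 for tetrachloroaniline replicate 2 with pentachloroaniline replicate 1 and to 11 for tetrachlorobenzene replicate 4 with 4-chloroaniline replicate 4.

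Between 3,5-dichloroaniline (76.8 µmol/kg) and 2,3,4-trichloroaniline (101.8 µmol/kg) no gene passed the threshold. Fcc01651 was lower after trichloroaniline by an estimate of -1.04 with a 95% interval of -1.5 to -0.58 (adjusted p 0.44), and Fcc00734 differed by -0.03 with an interval of -0.36 to 0.29 (adjusted p 0.99). By limma 0 probes differed, with 192 at an unadjusted p under 0.05, and the fit of separate channels in limma called 4. Blocking by slide gave 0 as well.

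From 2,3,4-trichloroaniline (101.8 µmol/kg) to 2,3,5,6-tetrachloroaniline (120.3 µmol/kg), sorting nexin-like Fcc01283 rose by a log2 of 2.62 ± 0.27 (adjusted p 0.0072), Fcc00563, similar to dopamine beta-hydroxylase, the enzyme that makes noradrenaline, by 2.04 ± 0.3 (adjusted p 0.022), cuticle protein 8-like Fcc03188 by 1.88 ± 0.22 (adjusted p 0.0072) and Fcc01651 by 1.6 ± 0.21 (adjusted p 0.0099). From there to pentachloroaniline (163.8 µmol/kg as labelled), Fcc01695 fell by 2.20 on the log2 scale (SE 0.21, adjusted p 0.0031), and Fcc01651 differed by -0.93 with a 95% interval of -1.39 to -0.46 (adjusted p 0.28). In limma 16 probes were higher after tetrachloroaniline than after trichloroaniline, with 580 at an unadjusted p under 0.05, and 1 probe, Fcc01695, differed between tetrachloroaniline and pentachloroaniline, with 347. The counts with a slide block were 0 and 2, with 0.98 ± 0.25 for Fcc01651 (adjusted p 0.41), 2.17 ± 0.42 for Fcc01283 (0.38), 2.31 ± 0.52 for Fcc00563 (0.39) and 1.77 ± 0.4 for Fcc03188 (0.39) in the first pair and -2.35 for Fcc01695 (adjusted p 0.0039) in the second. Within slides 2 and 3 Fcc01651 differed by 2.2 and 1.83 in the first pair. Without the array of trichloroaniline replicate 2 and tetrachloroaniline replicate 1 the first count was 0, without that of 4-chloroaniline replicate 2 and dichloroaniline replicate 1 or that of tetrachloroaniline replicate 2 and pentachloroaniline replicate 1 it was 10. It was 9 without that of pentachloroaniline replicate 2 and tetrachlorobenzene replicate 1, and 29 without that of control replicate 4 and dichloroaniline replicate 4. The call of Fcc01695 in the second pair was lost with Agilent's own log ratio (-2.29 ± 0.34, adjusted p 0.11), in the deposited table (-2.2 ± 0.3, 0.1) and with marked spots kept (-2.16 ± 0.28, 0.061). The second count was 0 without tetrachloroaniline replicate 2 with pentachloroaniline replicate 1, 2 without dichloroaniline replicate 2 with trichloroaniline replicate 1 or control replicate 4 with dichloroaniline replicate 4, and 3 without dichloroaniline replicate 3 with pentachloroaniline replicate 3.

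The mean of the 6 anilines was compared with tetrachlorobenzene to set polar against apolar compounds. Dopamine beta-hydroxylase-like Fcc00563 was higher in the anilines by a log2 of 1.69 ± 0.24 (adjusted p 0.023) and the undescribed gene Fcc05884 by 1.51 ± 0.17 (adjusted p 0.0099). The cytochrome P450 gene Fcc01651 was lower in the anilines by an estimate of -1.46 ± 0.16 (adjusted p 0.0099), Fcc01695 by -1.37 ± 0.16 (adjusted p 0.0099) and Fcc04190, similar to a carotenoid-cleaving dioxygenase, by -0.74 ± 0.09 (adjusted p 0.013). The mean covers labelled doses of 74.8 to 163.8 µmol/kg and holds the low values of Fcc01651 after aniline and 4-chloroaniline. By limma 8 probes differed, 5 higher and 3 lower in the anilines, with 360 at an unadjusted p under 0.05. Blocking by slide left 2, Fcc01651 (-1.57 ± 0.13, adjusted p 0.005) and Fcc01695 (-1.31 ± 0.12, adjusted p 0.0092), and Fcc00563 had 1.73 ± 0.27 (adjusted p 0.086). All 8 kept their direction within slide 2. The count was 2 without the array of pentachloroaniline replicate 2 and tetrachlorobenzene replicate 1, of tetrachlorobenzene replicate 2 and control replicate 1 or of tetrachlorobenzene replicate 4 and 4-chloroaniline replicate 4, and 0 without that of trichloroaniline replicate 4 and tetrachlorobenzene replicate 3.

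2,3,5,6-Tetrachloroaniline (120.3 µmol/kg) and 1,2,3,4-tetrachlorobenzene (163.8 µmol/kg as labelled) both carry 4 chlorine atoms and differ in the amino group and in where the chlorine atoms sit. The cytochrome P450 gene Fcc01651 differed by -0.04 on the log2 scale, with a 95% interval of -0.53 to 0.45 (adjusted p 0.96), and Fcc00734 by -0.07, with an interval of -0.42 to 0.27 (adjusted p 0.9). With slide as a block Fcc01651 stood at 3.19 after tetrachloroaniline and 3.77 after tetrachlorobenzene against the control. These values lay further apart than the 3.52 and 3.56 without the block. Higher after tetrachloroaniline were Fcc00563, similar to dopamine beta-hydroxylase (2.66 ± 0.32, adjusted p 0.0069), cuticle protein 8-like Fcc03188 (1.86 ± 0.24, adjusted p 0.0091) and the undescribed gene Fcc03049 (3.04 ± 0.55, adjusted p 0.042). Lower were dioxygenase-like Fcc04190 (-1.14 ± 0.13, adjusted p 0.0049), dynein heavy chain-like Fcc03136, a motor protein of microtubules (-1.01 ± 0.19, adjusted p 0.045), and Fcc05201, similar to the cohesin subunit SMC3 (-0.78 ± 0.14, adjusted p 0.039). By limma 32 probes differed, 23 higher and 9 lower after tetrachloroaniline, with 565 at an unadjusted p under 0.05. No probe (0) was called by limma with slide as a block, with 2.9 ± 0.5 for Fcc00563 (adjusted p 0.16) and -1.09 ± 0.19 for Fcc04190 (adjusted p 0.16). All 32 had their direction within slide 1 and within slide 2, where Fcc00563 differed by 2.71 and 1.94. Leaving out any 1 array gave 6 to 21 probes, except that of dichloroaniline replicate 2 and trichloroaniline replicate 1 (34), that of pentachloroaniline replicate 4 and aniline replicate 4 (34) and that of control replicate 4 and dichloroaniline replicate 4 (40).

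Gene lists were tested to see which groups of genes shifted as a whole. Of 133 tests of 19 lists in 7 compounds, 10 passed by camera with the preset correlation, 7 up and 3 down, and with an estimated correlation 0 passed (5 at an unadjusted p under 0.05), each of the 10 having adjusted p = 0.9 with an estimated correlation. Counting a gene once for each compound, the lists held 8 calls among all genes tested and 24 when adjusted over the list alone. By fry, which tests whether a list's genes move on balance one way, 0 tests passed, and by its mixed form, which tests change in either direction, 6 did. Median, mean and camera had the same sign in each of the 10, and all 10 passed with slide as a block. Leaving out 1 array gave 1 call without that of control replicate 4 and dichloroaniline replicate 4, 18 without that of 4-chloroaniline replicate 2 and dichloroaniline replicate 1 or that of tetrachloroaniline replicate 2 and pentachloroaniline replicate 1, 19 without that of aniline replicate 3 and trichloroaniline replicate 3, 20 without that of tetrachlorobenzene replicate 4 and 4-chloroaniline replicate 4, and 25 without that of tetrachloroaniline replicate 4 and control replicate 3.

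The list of cytosolic ribosomal proteins, 36 measured genes, shifted down after aniline: all 36 estimates were below 0, with a median of -0.224, and none of the genes was called singly (camera adjusted p 7.5e-08, adjusted p = 0.9 with an estimated correlation). In the same pools of whole animals the yolk list of 3 measured genes shifted up with a median of 0.9 (camera adjusted p 0.016, adjusted p = 0.9 with an estimated correlation). That list was fixed with ovary tissue in mind, but whether it follows the share of ovary was not tested. A change in the share of tissues was not separated from a change within cells. Fcc05736, ribosomal protein L35e-like, stood at -0.26 ± 0.1 and Fcc04265, L11-like, at -0.34 ± 0.14. Within slides 1 and 2 the medians were -0.278 and -0.565. After dichloroaniline 31 of the 36 were below 0 with a median of -0.089 (adjusted p 0.011, adjusted p = 0.9 with an estimated correlation), and the median within slide 2 was -0.133. Of 29 alternatives, 29 kept the shift after aniline past the threshold and 23 kept that after dichloroaniline, where the median ran from -0.196 to -0.004 and the adjusted p up to 0.64. The list holds 5 genes that match mitochondrial or organelle-type ribosomal proteins or a kinase, and without them, a choice made after seeing the data, the adjusted p after aniline was 1.1e-07. Over the trend in chlorine number, 29 of 36 estimates were above 0 with a median of 0.036 per chlorine atom (adjusted p 0.0015, adjusted p = 0.79 with an estimated correlation).

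The cytochrome P450 genes, 13 measured, shifted up after dichloroaniline (11 above 0, median 0.11, adjusted p 0.011), trichloroaniline (10 above 0, 0.266, 0.011) and pentachloroaniline (11 above 0, 0.261, 0.011), each with adjusted p = 0.9 with an estimated correlation. Within the list Fcc01651 was the only gene called, in 5 compounds over all genes tested and in 6 when adjusted over the list alone. Other members were Fcc00266 (1.29 ± 0.42 after dichloroaniline, adjusted p 1), Fcc02595, similar to CYP15A1, an enzyme of juvenile hormone synthesis (1.03 ± 0.29 after aniline, adjusted p 0.41), and Fcc04064, similar to CYP4C1 (0.54 ± 0.32 after tetrachloroaniline, adjusted p 0.45). Without Fcc01651, left out after seeing the data, the 3 adjusted p-values were 0.17, 0.12 and 0.13. Within slide 2 the medians after dichloroaniline, trichloroaniline and pentachloroaniline were 0.284, -0.131 and 0.545, the second of opposite sign, and within slide 1 the median after pentachloroaniline was 0.045. The shift passed in 27 of 29 alternatives after dichloroaniline, where the median ran from -0.026 to 0.19 and so turned in sign, with adjusted p up to 0.59. It passed in 23 of 29 after trichloroaniline and in 25 of 29 after pentachloroaniline.

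The 7 cuticle, chitin and moulting genes shifted up after tetrachloroaniline, all 7 above 0 with a median of 0.456 (adjusted p 0.011, adjusted p = 0.9 with an estimated correlation). Cuticle protein 8-like Fcc03188 was called over all genes tested, and 3 genes were when adjusted over the list alone; cuticle protein 2-like Fcc04335 had 1.07 ± 0.22 (adjusted p 0.066) and chitinase-like Fcc02129 0.46 ± 0.14 (adjusted p 0.14). Within slides 1 and 2 the medians were -0.014 and 0.536. The 3 yolk genes were all above 0 after aniline (median 0.9, adjusted p 0.016, adjusted p = 0.9 with an estimated correlation; within slides 1 and 2 0.862 and 0.349) and after trichloroaniline (median 0.459, adjusted p 0.04, adjusted p = 0.9 with an estimated correlation; within slide 2 0.071). Other phase I enzymes, such as carboxylesterase-like Fcc01181, shifted up after trichloroaniline with 8 of 9 above 0 and a median of 0.375 (adjusted p 0.013, adjusted p = 0.9 with an estimated correlation), but within slide 2 the median was -0.439. Digestive enzymes shifted down after dichloroaniline with 14 of 18 below 0 and a median of -0.214 (adjusted p 0.041, adjusted p = 0.9 with an estimated correlation), and the median within slide 2 was -0.105. This digestive shift passed in 17 of 29 alternatives, with a median of -0.336 to -0.032 and an adjusted p up to 0.32. The cuticle shift passed in 28 of 29, the yolk shift in 28 of 29 after aniline and 20 of 29 after trichloroaniline, and that of other phase I enzymes in 23 of 29.

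In the other 13 lists no camera test passed. The lowest adjusted p was 0.058 for the 15 glutathione S-transferases (trichloroaniline, 12 above 0), where Fcc05260 after tetrachloroaniline was the only call over all genes tested, and 3 compounds had 1 call each when adjusted over the list alone. It was 0.059 for oxidative phosphorylation (tetrachlorobenzene), 0.079 for proteasome and ubiquitin (aniline), 0.09 for beta-lactam synthesis (pentachloroaniline), 0.11 for innate immunity (pentachloroaniline), 0.15 for chaperones (tetrachlorobenzene) and 0.2 for both muscle and lipid metabolism. For glycolysis and citrate cycle it was 0.22, for nerve and ion transport 0.26, for DNA repair and histones 0.37 and for both antioxidant enzymes and microbes 0.5. UDP-glycosyltransferases had 2 measured genes, Fcc02716 (0.62 ± 0.15 after tetrachloroaniline, adjusted p 0.083) and Fcc01065 (-1.02 ± 0.51, adjusted p 0.35), and were not tested, nor were ABC transporters (1 measured, Fcc05098, -1.28 ± 0.57 after tetrachlorobenzene, adjusted p 0.97), metal binding (1 measured, the ferritin-like Fcc04961, -0.17 ± 0.11 after aniline, adjusted p 0.67), sulfo- and acetyltransferases (0 measured) and apoptosis (0 measured). The word pattern for ABC transporters did not take in Fcc04544, described as an ATP dependent transmembrane transporter. That gene was called after dichloroaniline, tetrachloroaniline and tetrachlorobenzene.

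Similarity of the responses was asked of all 21 pairs of compounds. Called genes were shared 61 times over the pairs, 59 up and 2 down, against a mean of 1.03 in simulations of unchanged groups with the same controls. Without any effect, these simulations called a mean of 37.6 probes over the 7 compounds and up to 1147 in a single run. The mean thus hides a wide spread between runs, and runs with at least 61 shared calls were not counted. Dichloroaniline and tetrachlorobenzene shared 7 of their 8 and 8 higher genes, Fcc01651 and Fcc01695 among them, where independent lists without common controls would share 0.014, and tetrachloroaniline and tetrachlorobenzene shared 7, where independent lists would share 0.036. Over all probes the mean r of the fold changes was 0.49 (0.28 to 0.75), and unchanged groups against these controls gave a mean r of 0.46 with 44 of 100 simulations as high. The mean covariance was 0.065 beside a simulated 0.049, a difference of 0.015, and for 0 pairs was the covariance above all simulations. With the controls split between the 2 compounds of a pair, the mean r was -0.09 beside a simulated -0.15. The correlations are across genes, which are not independent replicates. Without the array of tetrachlorobenzene replicate 2 and control replicate 1 the mean r over all probes was 0.67.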

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

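In 10 genes and 8 groups, 80 groups of 4 samples were tested for a sample far from the other 3, and 6 had one. Chance alone gives about 1 in 20, or 4 here. The cytochrome P450 gene Fcc01651 stood at a log2 intensity of 12.25 in tetrachloroaniline replicate 1, where the other 3 samples had 10.81 to 11.02, and at 10.69 in pentachloroaniline replicate 3, where the others had 10.06 to 10.16. In both, the high sample lies above the others on a side away from the control. Fcc05067 had 10.47 in dichloroaniline replicate 2 (others 11.41 to 11.46) and Fcc02155 had 12.18 in trichloroaniline replicate 4 (others 12.73 to 12.82). Beta-lactam synthesis genes gave the last 2: Fcc00170 had 11.53 in tetrachloroaniline replicate 4 (others 8.74 to 9.06) and Fcc01821 had 13.54 in pentachloroaniline replicate 4 (others 9.58 to 10.16).

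In pentachloroaniline replicate 4 the 3 beta-lactam synthesis genes Fcc00057, Fcc00170 and Fcc01821, whose best matches make penicillin-like antibiotics in fungi and bacteria, lay 3.41 to 4.06 above the mean of the other 3 samples on the log2 scale. The 3 tests of this pattern had their predictions written before they were run. A blemish on single spots did not account for it, since the 3 spots of a probe spanned at most 0.49. A shift of the whole sample did not either, since 19 of 4447 probes, 0.43%, lay more than 2 above the other samples. RNA of microbes could not be told apart, because the median of the microbe list lay 0.06 above the other samples but that list holds likenesses to microbial genes and not genes known to be microbial. Of the 19 raised probes, Fcc01758 (3.36), Fcc05180 (2.66), Fcc00343 (3.88) and Fcc05098 (2.22) also best matched bacterial or fungal sequences. Fcc00086, Fcc01574, Fcc03484 and Fcc06001 matched animal sequences, and the others beside the 3 genes had no description. These probes were picked out after their values were seen. No biological explanation was tested.

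Spike-in control probes, which no comparison used, were bright on the array of 4-chloroaniline replicate 2 and dichloroaniline replicate 1, with a median log2 signal of 17.92 in Cy3 and 14.28 in Cy5 over 10 probes in 200 spots. The other 15 arrays had 6.58 to 7.64 in Cy3 and 8.18 to 9.37 in Cy5. Both tests of this signal were chosen after it was seen. The array as a whole was not brighter, with a Cy3 median of 5.61 in the negative control spots beside 5.55 to 5.72 on the others, which argues against brightness of the whole array. Leakage of this signal into probes of the animals stays open, because the array weight of 2.17 rests on all probes and would hardly change if a few took it up. No biological explanation was tested.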

How the results depend on the processing

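Of 90 values of named genes that were called, none reversed under any alternative, and leaving out 1 array kept 46 to 78 of the 90 past the threshold. The naming rule asked for the same sign in each of the 16 fits that leave out 1 array. The lack of reversals in those fits was thus largely set in advance. Most other alternatives refitted the same arrays for probes already called. Kept were 90 with Aquantile, 88 in the authors' deposited table, 87 with a trend and robust prior, 87 with marked spots kept, 85 with array weights, 84 with no background correction, 81 of 82 with only probes well above background in all 32 channels, 81 with no filter, 75 with Agilent's own log ratio, 73 in separate channels, 65 with no dye term, 61 without the 2 arrays farthest apart in the residuals and 31 with slide as a block. The slide block let the dye term differ between slides, at a cost in residual degrees of freedom. Calls lost with it do not by themselves show that a difference depended on the slide. The number of arrays and the signal over background limit what can be called. No paired analysis was possible because the labels give no replicate numbers that tie samples of different groups together. All probes in place of the brightest probe per gene was not run, since each gene name had 1 probe. For the values below that changed, the cause was not tested except where it is stated.

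With no background correction the trend had 10 probes. With Agilent's own log ratio tetrachloroaniline had 46, the trend 8, the anilines against tetrachlorobenzene 5 and tetrachloroaniline against tetrachlorobenzene 18. With no filter on dim probes the trend had 3. Tetrachloroaniline against pentachloroaniline had 0 with only probes well above background in all 32 channels, 0 in the authors' deposited table and 0 with marked spots kept. The stricter filter had taken out Fcc01695, the only call of that comparison, so its 0 says nothing about the difference. With no dye term tetrachloroaniline against tetrachlorobenzene had 11, aniline against 4-chloroaniline 5, trichloroaniline against tetrachloroaniline 7 and the gene lists 17. With array weights 4-chloroaniline had 31, tetrachloroaniline 184, the trend 49, tetrachloroaniline against tetrachlorobenzene 79, aniline against 4-chloroaniline 84, 4-chloroaniline against dichloroaniline 24 and any compound 40.

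With slide as a block 4-chloroaniline had 0, trichloroaniline 3, tetrachloroaniline 10, the trend 2, the anilines against tetrachlorobenzene 2, tetrachloroaniline against tetrachlorobenzene 0, aniline against 4-chloroaniline 0, 4-chloroaniline against dichloroaniline 1, trichloroaniline against tetrachloroaniline 0 and tetrachloroaniline against pentachloroaniline 2. In separate channels aniline had 6, 4-chloroaniline 14, dichloroaniline 19, trichloroaniline 20, tetrachloroaniline 175, pentachloroaniline 23, tetrachlorobenzene 16, the trend 131, tetrachloroaniline against tetrachlorobenzene 169, aniline against 4-chloroaniline 21, 4-chloroaniline against dichloroaniline 13, dichloroaniline against trichloroaniline 4, trichloroaniline against tetrachloroaniline 140, tetrachloroaniline against pentachloroaniline 3, any compound 130 and the gene lists 18. There the uncalled estimate of Fcc02155 after aniline was 0.11 in place of -0.19.

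Without the 2 arrays farthest apart in the residuals, chosen after seeing the data, 4-chloroaniline had 4, trichloroaniline 4, the trend 10, the anilines against tetrachlorobenzene 3, tetrachloroaniline against tetrachlorobenzene 8, aniline against 4-chloroaniline 14, 4-chloroaniline against dichloroaniline 13, tetrachloroaniline against pentachloroaniline 4 and any compound 13. With 1 adjustment over the 7 compounds tetrachloroaniline had 15. With the P450 list short of Fcc01651, also chosen after seeing the data, the gene lists had 5 calls.

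Leaving out 1 array at a time gave 0 to 3 for aniline, 0 to 4 for 4-chloroaniline, 4 to 11 for dichloroaniline, 4 to 7 for trichloroaniline, 6 to 71 for tetrachloroaniline, 2 to 6 for pentachloroaniline, 5 to 11 for tetrachlorobenzene, 2 to 21 for the trend, 0 to 10 for the anilines against tetrachlorobenzene, 6 to 40 for tetrachloroaniline against tetrachlorobenzene, 0 to 27 for aniline against 4-chloroaniline, 0 to 11 for 4-chloroaniline against dichloroaniline, 0 to 29 for trichloroaniline against tetrachloroaniline, 0 to 3 for tetrachloroaniline against pentachloroaniline, 10 to 22 for any compound, 1 to 25 for the gene lists and 0.42 to 0.67 for the mean r. Uncalled estimates that changed sign were those of Fcc04325 after tetrachloroaniline (-0.42 to 0.06), Fcc04961 after aniline (-0.21 to 0.01), Fcc00734 after aniline (-0.01 to 0.32) and Fcc02155 after aniline (-0.44 to 0.24).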

Other observations

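The tests of dye, of dose and of other splits in this part were chosen after the results were seen, whereas those of slides and of shared probe sequence had predictions written before they were run. A second set of genes followed a different order of compounds from the shared response, a pattern picked out after the values were seen. Fcc03768 had a log2 fold change of 2.18 after 4-chloroaniline and 1.97 after tetrachloroaniline (adjusted p 0.0042) but 0.38 after trichloroaniline and 0.11 after tetrachlorobenzene, and Fcc05884 had 2.08 and 2.09 (adjusted p 0.0015) but 0.17 and -0.32. The other compounds lay between, with 1.47, 0.84 and 1 for Fcc03768 and 1.17, 0.93 and 0.69 for Fcc05884 after aniline, dichloroaniline and pentachloroaniline. Cuticle protein 8-like Fcc03188 had 1.25 and 1.38 in the first pair of compounds and -0.50 and -0.48 in the second. Dopamine beta-hydroxylase-like Fcc00563 had 1.04 and 1.14 (adjusted p 0.098), against -0.89 and -1.51. The cause of the pattern was not tested. With slide as a block the calls after 4-chloroaniline were lost in limma, with 2.28 ± 0.28 for Fcc03768 (adjusted p 0.12) and 2.08 ± 0.37 for Fcc05884 (0.48) beside 2.18 ± 0.25 and 2.08 ± 0.23 without it.

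The mean of all 7 compounds against the control was added after seeing the data. By limma 6 probes rose and 0 fell, with 245 at an unadjusted p under 0.05: Fcc01695 (2.72 ± 0.16, adjusted p 3.4e-05), Fcc01651 (2.31, 9.5e-05), Fcc00734 (1.17, 0.00092) and the transporter-like Fcc04544 (1.03, 0.039), and, chosen after their values were seen, Fcc02906 (2.03, 0.00054) and Fcc05067 (1.88, 0.00092). In 5 comparisons the number of probes at an unadjusted p under 0.05 was below the 222 that even p-values would give: dichloroaniline 115, trichloroaniline 148, pentachloroaniline 214, tetrachlorobenzene 182 and dichloroaniline against trichloroaniline 192.

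A rise shared by the 5 probes Fcc01651, Fcc01695, Fcc02906, Fcc05067 and Fcc00734 after the 5 compounds with at least 2 chlorine atoms was weighed against technical causes. Dye bias did not account for it, since all 50 of 50 differences from the control within 1 dye lay above 0. A difference between slides did not either, since 40 of 40 estimates within slides lay above 0, at 1.31 or more in slide 1 and 1.26 or more in slide 2. For the tests of dye and slide, the 5 probes had been chosen from a fit that held these samples. The probes held no long common sequence, the longest run shared by a pair being 8 bases. Probes for different parts of 1 transcript need share no run, so this cannot exclude 1 transcript behind several of the 5 probes. From 4-chloroaniline (74.8 µmol/kg) to dichloroaniline (76.8 µmol/kg) the median difference of the 5 probes was 1.46 (0.77 to 2.32). Their choice partly set this step, since they were called after dichloroaniline and not after 4-chloroaniline. By limma over all probes Fcc01695 (adjusted p 0.0018) and Fcc01651 (0.01) differed, so labelled molar dose alone did not account for their step. Fcc02906 (0.051), Fcc00734 (0.12) and Fcc05067 (0.36) did not pass, and with slide as a block Fcc01651 had 0.62. A response to chlorinated compounds that raises a cytochrome P450 gene remains possible and was not tested. It would not be particular to polar narcosis, since tetrachlorobenzene raised Fcc01651 by 3.56.

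Other splits of the same samples were tried for each comparison, counting those with at least as many calls as the real one, itself included. With 35 splits, 1 of 35 is the lowest share that can come out. The shares were not adjusted over the comparisons. The splits did not keep the dyes balanced between the sides. They also mixed the groups compared, so a real difference added to the errors of the other splits. Low counts in the other splits were thus partly set by the design and do not exclude chance. Only the real split reached its count for dichloroaniline (1 of 35 splits, 9 probes, highest other 1), trichloroaniline (1 of 35, 7 probes, highest other 2), tetrachloroaniline (1 of 35, 30 probes, highest other 5), pentachloroaniline (1 of 35, 6 probes, highest other 5), tetrachlorobenzene (1 of 35, 8 probes, highest other 0) and 4-chloroaniline against dichloroaniline (1 of 35, 4 probes, highest other 1). The same held for any compound (1 of 100, 21 probes, highest other 2) and for the trend (1 of 100, 17 probes, highest other 2), although the trend had 2 probes with slide as a block. For the anilines against tetrachlorobenzene 2 of 100 splits had as many (8 probes, highest other 20). Those splits mixed all 7 compounds, so differences among the anilines entered them too, and they cannot exclude chance for this comparison. The split with 20 calls followed no slide and points to a structure among the samples, and with slide as a block 2 probes were called.

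The splits took no account of slide. Only the real split reached its count, again the lowest share, for tetrachloroaniline against tetrachlorobenzene (1 of 35, 32 probes, highest other 0), aniline against 4-chloroaniline (1 of 35, 3 probes, highest other 0) and trichloroaniline against tetrachloroaniline (1 of 35, 16 probes, highest other 8). In these 3 comparisons 0 probes were called by limma with slide as a block. The calls ended mostly with larger errors and not with smaller folds: Fcc00563 had 2.9 ± 0.5 beside 2.66 ± 0.32 in the first, Fcc01381 3.61 ± 0.53 beside 3.46 ± 0.41 in the next and Fcc03188 1.77 ± 0.4 beside 1.88 ± 0.22 in the last, although Fcc01651 there had 0.98 ± 0.25 beside 1.6 ± 0.21. All 32, 3 and 16 calls kept their direction within each slide that gave an estimate, but their choice from a fit of the same arrays largely set this. Another split had at least as many calls for tetrachloroaniline against pentachloroaniline (2 of 35, 1 probe, highest other 1) and for 4-chloroaniline (2 of 35, 2 probes, highest other 60). In the latter the split with 60 calls put all samples of slide 2 on 1 side, which points to a structure among the samples, and with slide as a block the folds of Fcc03768 and Fcc05884 stayed as given above while limma called 0. Aniline (35 of 35, highest other 5) and dichloroaniline against trichloroaniline (35 of 35, highest other 9) had 0 calls, so all splits had as many and the count says nothing about chance. The highest split for aniline set all Cy3 samples against all Cy5 samples.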
